A study of Homo sapiens with 4 samples.

How the data were processed

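Total RNA from MIA PaCa-2 cells was amplified, labelled with Cy3 and hybridised to Agilent gene expression arrays, 1 array for each of the 4 groups (Control, HSA, HBD2 and ADDC), per the labels' protocols. Spot intensities were extracted by the authors with Agilent Feature Extraction 11.0.1.1, per the file headers, which also name hg19 as the annotation of the probe design. The deposited processed signal is an intensity after local background subtraction and detrending within the array, per the file headers. The deposited files also hold other columns, the flags for outliers, saturation, control type and signal well above background, which were used as filters. The deposited series table holds log2 values with the same quartiles in every column (a median of 6.74 on every array), and its steps are not given in the sources used here. Each of its columns correlated with log2 processed signal of the same array at Pearson's r between 0.997 and 0.999, so its scale is log2, it is not centred by gene, and it appears quantile normalized.

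The main values were log2 of the processed signal minus the array's 75th percentile, after control spots and outlier spots were left out and the spots of a probe averaged. No spot was saturated. Each array held 44495 spots, of which 1377 were control spots, and 34127 probes, 999 of them printed 10 times. The files give accessions and no gene symbols. Of 26599 probes with a RefSeq accession, 25769 were named through the given RefSeq table of assembly GRCh38.p14, used for names only; 25771 probes had a symbol in all, for 19740 genes, and 8356 had none and are outside the gene counts. A gene was represented by its probe with the highest mean level, and where its probes disagree this is stated for named genes. A probe was measured in a comparison if it was well above background on both arrays. A gene well above background on 1 array only has a bound, the bright level against the higher of the dim probe's own level and the lowest level of a probe well above background on the dim array.

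With 1 array per group there is no test. Genes were counted at 2-fold, and the spread between spots of the same probe was used as technical error, with median SDs within an array of 0.054 to 0.056 on Control, HSA and HBD2 and 0.069 on ADDC. All 4 arrays lay on 1 slide, so slide and scan do not separate the groups, but position on the slide and group cannot be told apart. Probes for spiked-in control RNA had median signals of at most 59.9 on Control and 34.3 on ADDC. The labels' protocols mention no added RNA and these probes were not used as an outside scale, so a change in total messenger RNA per cell would not be seen. RNA purity and integrity were checked by spectrophotometry and gel, per the labels' protocols, and no values are given.

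Named genes follow a rule fixed before the data were examined. It takes the 10 genes with the largest difference in each direction per comparison with Control whose probes all go the same way and whose level is at or above the 25th percentile of measured probes, 10 genes each way apart from all other arrays, 5 genes each way with the largest bounds, 4 members of each of 36 gene lists with the largest difference, and some genes fixed by name, among them ALB, DEFB4A, CCR6, FCGRT and SPARC. A gene with 1 measured probe meets the condition on agreement of probes. Not every gene or list that the naming rule covers is given. Other genes that are named were chosen after their values were seen. A list is given as its median difference with its percentile among 10000 random lists of the same size matched on level in 20 classes, and percentiles under 2.5 or over 97.5 are described as standing apart in these arrays. Percentiles of gene families grouped by symbol, olfactory receptor genes among them, come from 2000 such random lists.

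Alternatives fixed beforehand were normexp background correction (offset 50, on the median signal, since the files hold no mean signal) with quantile normalization, quantile normalization, centring on the median of probes well above background on all arrays, cyclic loess (3 iterations), the deposited series table, all probes with a floor, genes at or above the median level only, the mean over a gene's probes, saturated spots kept, and thresholds of 1.5-fold and 3-fold. The calculations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. They were tested on simulated arrays with spot noise for the comparison of ADDC with Control (15977 genes), where 48 of 50 genes changed 2.5-fold, 50 of 50 changed 4-fold, 50 of 50 changed 8-fold, 0 of 50 changed 1.5-fold and 50 of 15777 unchanged genes were counted at 2-fold. For the comparison of HSA with Control (16852 genes), 5 of 100 unchanged lists of 20 genes stood apart, and 91 and 100 of 100 did when shifted by 0.1 and 0.2 on the log2 scale. The simulated genes varied independently, while members of a real list vary together, so these shares need not hold for real lists.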

Results

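Gene expression was measured in MIA PaCa-2 cells, an established human pancreatic carcinoma line, on 4 one-colour Agilent arrays. The stated purpose of the series was to learn how the agent called ADDC acts on these cells and which genes it targets, within a project on carrying therapeutic peptides with albumin. The cells were left untreated (Control) or were treated with ADDC, HSA or HBD2, and each of the 4 groups had 1 array. The design text gives 15 μM and does not make clear whether this concentration applied to all 3 agents, and it does not spell out the abbreviations. No group had a replicate, so none of the differences below has a replicate check, no p-value is given, and the number of arrays limits the precision. The error printed beside a gene is the scanner software's estimate for a difference between 2 arrays, and it covers measurement of the array only. It was near 0.204 for one bright gene after another, and it is not the spread between spots of that gene.

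The arrays differed in brightness. The 75th percentile of the processed signal was 1041 on the Control array, 879 on HSA, 725 on HBD2 and 596 on ADDC. Spots well above background made up 83.9% of non-control spots on Control, 84.2% on HSA, 82.7% on HBD2 and 77.9% on ADDC. Across genes, the Control, HSA and HBD2 arrays correlated with each other at Pearson's r of 0.997 to 0.998, while the ADDC array correlated with them at 0.948 to 0.950. Genes are not independent replicates, and these coefficients describe the arrays only.

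The comparison of ADDC with Control asks which transcripts differed in cells given ADDC. The gene with the largest difference by the naming rule was the nuclear receptor gene NR4A1, higher on the ADDC array at 158-fold (log2 difference 7.31 ± 0.21, measurement error). The next were MAFF, a small MAF transcription factor, at 45.7-fold (5.52 ± 0.20), MSMO1, an enzyme of cholesterol synthesis, at 37.2-fold (5.22 ± 0.20), CDKN1C, a cyclin-dependent kinase inhibitor, at 35.3-fold (5.14 ± 0.20) and PHLDA2 at 33.5-fold (5.07 ± 0.20). CREB3L3 was 24.9-fold higher, the inducible chaperone gene HSPA1B 24.7-fold, the stress cytokine gene GDF15 23.9-fold, and HMOX1, which encodes haem oxygenase 1, 22.9-fold. INF2 was 28.4-fold higher at its brightest probe, but its 3 probes ranged from 0.26 to 4.83 on the log2 scale. Lower on the ADDC array were ZNF75A at 44.3-fold (-5.47 ± 0.28), ELAC1 at 30.3-fold (-4.92 ± 0.25), PPP1R10 at 27.0-fold (-4.75 ± 0.23), ZFHX2 at 25.8-fold (-4.69 ± 0.28) and TNFSF10, the gene of the death ligand TRAIL, at 22.2-fold (-4.47 ± 0.21) at its brightest probe and -2.65 at the other. ZNF658, PRMT6, ZNF594, NAIP and ZNF189 were each between 18.7-fold and 20.1-fold lower. Apart from INF2, TNFSF10 and ZNF658, each gene named here had 1 measured probe, so agreement between probes could not be checked. On the ADDC array several of the lower genes lay near the low end of the scale, with ZNF75A at -4.27 and NAIP at -4.70 relative to the 75th percentile. TNFSF10 was at -2.45.

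**Figure D1:**
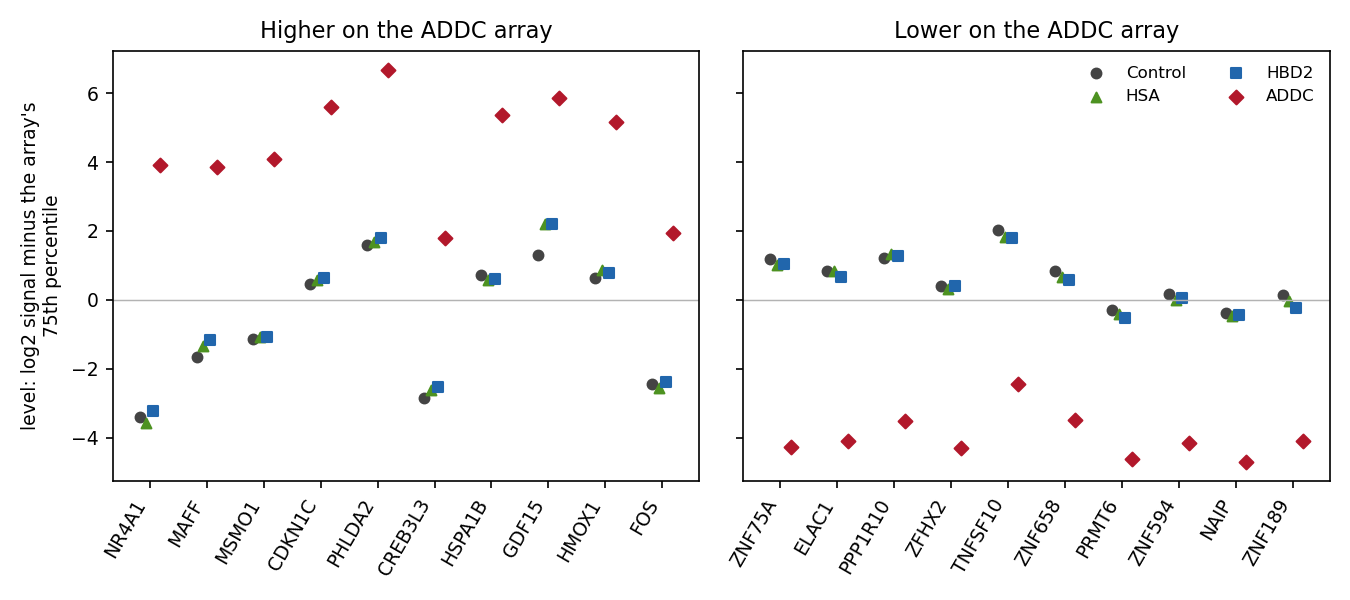
Levels of 10 genes higher and 10 genes lower on the ADDC array, as log2 signal minus the array's 75th percentile (vertical axis), with 1 point per array. For NR4A1 the ADDC point lies at 3.91 and the Control point at -3.40, and the Control, HSA and HBD2 points of a gene lie within 1 log2 unit, widest for GDF15 (HSA 0.92 above Control); levels of different genes come from different probes and are not comparable.

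Of 15977 genes measured on both arrays, 1286 were at least 2-fold higher on ADDC and 1758 at least 2-fold lower, 19.1% in all. At least 4-fold differences were seen for 217 genes in the higher and 389 in the lower direction. The median difference over all genes was 0.17, and counted relative to that median 918 genes were higher and 2187 lower; after cyclic loess, which brought the median to 0.02, the counts were 880 and 2033, so that the higher share went from 42.2% to 30.2%. Other settings moved it the opposite way, to 1540 higher and 1570 lower (49.5%) when centred on the median of detected probes and to 869 and 838 (50.9%) with only genes at or above the median level, so which direction held more genes depended on the setting. Single spots of probes printed 10 times had a technical SD of 0.17 for this difference, and 160 of 790 such probes (20.3%), each averaged over its spots, were at least 2-fold apart. Of 739 genes in the count that had several measured probes, 223 had probes that differed in sign, and 57 of 3625 genes with several probes had probes at least 2-fold apart in opposite directions. A further 1062 genes were well above background on Control and not on ADDC, 200 of them with a bound of at least 2-fold, against 80 with the opposite pattern, 45 of them past that bound. The largest such bounds on ADDC were at least 39.2-fold lower for VXN and at least 13.8-fold higher for ZNF204P. For HBD2, 342 genes were well above background on Control only and 146 on HBD2 only, with 10 and 13 past a 2-fold bound. For HSA the numbers were 202 and 234, with 10 and 8 past it.

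**Figure D2:**
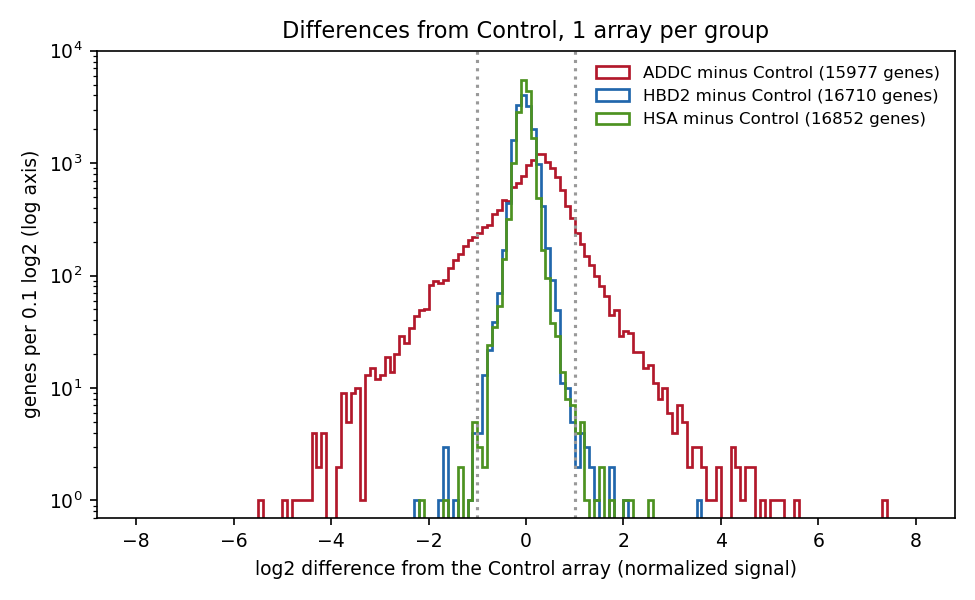
Distribution of the log2 difference from the Control array over measured genes for ADDC (15977 genes), HBD2 (16710) and HSA (16852), in classes of 0.1 with a logarithmic count axis; dotted lines mark a 2-fold difference. The ADDC distribution is wide, with 1286 genes to the right of the lines and 1758 to the left, and those of HBD2 and HSA have 27 genes each outside the lines.

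The immediate-early genes, which cells switch on within minutes of a stimulus, were the group with the highest median on the ADDC array. Of 20 measured members, 12 were at least 2-fold higher and none was 2-fold lower, with a median log2 difference of 1.85, above all 10000 random lists of the same size and level. Over the alternatives its median ran from 1.23 to 2.16, with 7 to 13 members higher. FOS was at 4.38, ZFP36 at 4.30 and DUSP1 at 4.29, whereas EGR1 was at -0.29 and JUN at -0.10. The 36 lists were fixed before the data were examined, and the percentile of a list describes these arrays only, since members of a list vary together and random genes do not.

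Protein-folding genes of the cytosol and of the endoplasmic reticulum were higher together. Of 16 heat shock genes, 12 were at least 2-fold higher and none 2-fold lower (median 1.35, percentile 100; over the alternatives 0.893 to 1.5025, with 5 to 13 members higher), among them DNAJB1 at 2.58, HSPH1 at 2.15 and CHORDC1 at 1.82. HSPA1B was at 4.63 and its near-identical copy HSPA1A at -0.38, and since probes may not tell these apart both values are uncertain. Of 18 genes of the unfolded protein response, 12 were at least 2-fold higher and none was lower (median 1.23, percentile 100; over the alternatives 0.82 to 1.31, with 7 to 12 members higher). They included the chaperone partners DNAJB9 at 3.04, SDF2L1 at 2.79 and DNAJC3 at 2.54, and the transcription factor gene DDIT3 at 2.84. The proteasome list had a median of 0.60, with 3 of 29 members at least 2-fold higher, and lay at percentile 95.1; under cyclic loess its median was 0.22 at percentile 98.7, where it stood apart. The autophagy and lysosome list had 6 of 23 members at least 2-fold higher (median 0.53, percentile 98.9; over the alternatives 0.24 to 0.64, with 4 to 6 members higher), with GABARAPL1 at 2.69, MAP1LC3B at 2.67 (1.06 at its other probe) and SQSTM1 at 2.18, but it lay at percentile 96.7 under quantile normalization.

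Of 18 NRF2 targets, which respond to oxidative stress, 8 were at least 2-fold higher and 1 was lower (median 0.96, percentile 99.99; over the alternatives 0.496 to 1.04, with 5 to 10 members higher). HMOX1 was at 4.52. AKR1C1 at 2.45 and AKR1C3 at 2.29 are close relatives, so their probes do not surely separate them, and the other probe of AKR1C1 was at 0.31. The lower member was the cystine transporter gene SLC7A11 at -1.72. The list of the integrated stress response and amino acid response went both ways, with 7 of 22 members at least 2-fold higher and 2 lower (median 0.55, percentile 95.1); it stood apart on the high side with only the brighter genes (0.74, 99.7) and with the mean of probes (0.71, 99.8). GDF15 was at 4.58, DDIT3 at 2.84 and CEBPB at 2.14, while CHAC1 was at -1.83 and SLC7A11 at -1.72. In the metallothionein and zinc export list 1 of 11 members passed 2-fold, the zinc exporter gene SLC30A1 at 2.29 (median 0.42, percentile 41.3).

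Mitotic genes were higher on the ADDC array. Of 22 members of the G2/M list, 11 were at least 2-fold higher and 1 was lower (median 0.98, percentile 100; over the alternatives 0.54 to 1.06, with 4 to 12 members higher), with CDK1 at 1.97, CCNA2 at 1.51 and TTK at 1.48 against KIF11 at -1.10. The G1/S list did not stand apart, with 2 of 26 members at least 2-fold higher and a median of 0.23 (percentile 50.7). In homologous recombination repair 4 of 16 members were at least 2-fold lower and 1 was higher (median -0.29, percentile 8.2), and the lower ones were PALB2, BRIP1 at -1.81, BRCA2 at -1.80 and BRCA1 at -1.66. Ribosome biogenesis genes had 5 of 21 members at least 2-fold higher, including NOP16 at 1.19 and DKC1 at 1.13, and stood apart (median 0.71, percentile 99.7; over the alternatives 0.31 to 0.79, with 1 to 6 members at least 2-fold higher). Cytoplasmic ribosomal protein genes had a median of 0.62 with none of 27 past 2-fold (percentile 76.0), and under cyclic loess their median was -0.08.

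Cholesterol synthesis genes were higher as a group, with 6 of 21 members at least 2-fold higher and none lower (median 0.70, percentile 99.9; over the alternatives 0.31 to 0.79, with 6 to 9 members higher). MSMO1 was at 5.22, INSIG1 at 3.47 and HMGCS1 at 2.62. Of 14 fatty acid synthesis genes 1, ACSL3 at -1.01, passed 2-fold (median -0.05, percentile 6.1); under normexp with quantile normalization, quantile normalization, cyclic loess and the deposited table the median was -0.43 to -0.49 and the list stood apart on the low side. Also, of 15 fatty acid oxidation and PPAR target genes 5 were higher and 1 lower (median 0.27, percentile 63.9), with CREB3L3 at 4.64 and CPT2 at -2.08. Hypoxia and glycolysis genes had 7 of 20 members at least 2-fold higher and none lower (median 0.65, percentile 99.97; over the alternatives 0.42 to 0.74, with 4 to 8 members higher), among them PFKFB3 at 2.49 and VEGFA at 2.29 at its brightest probe and 4.88 at the other; with only the genes at or above the median level kept, the list lay at percentile 94.8. None of 26 oxidative phosphorylation subunit genes passed 2-fold (median 0.43, percentile 45.7).

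Of 19 NF-kB targets and inflammatory cytokine genes, 5 were at least 2-fold higher and 1 was lower (median 0.56, percentile 99.7; over the alternatives 0.21 to 0.99, with 1 to 8 members higher), with CXCL8 at 2.44, TNFAIP3 at 1.73, NFKBIA at 1.52 and CCL20 at -2.29. Interferon-stimulated genes were lower, with 5 of 17 at least 2-fold lower and none higher (median -0.31, percentile 1.9). IFIT2 was at -3.60, MX1 at -1.82, BST2 at -1.77 and IFIT3 at -1.73. The median of that list was 0.18 and lay at percentile 51.5 when only the brighter genes were kept, and the list lay at percentile 2.63 under normexp with quantile normalization.

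Death and survival genes did not stand apart as groups in the main setting. Of 19 pro-apoptotic genes 2 were at least 2-fold higher and 4 lower (median 0.38, percentile 90.8; 0.49 and 98.8 with the mean of probes, where it stood apart), with BBC3 at 2.71 and BAK1 at 2.16 against CASP8 at -1.92 and CASP6 at -1.61. Of 11 anti-apoptotic genes 2 were higher, MCL1 at 2.09 and BAG1 at 1.42 (median 0.20, percentile 53.9). In the list of RAS-ERK output 3 of 19 members were higher and 5 lower (median 0.04, percentile 20.3), with DUSP5 at 3.77 and FOSL1 at 2.32 against EPHA4 at -1.51 and DUSP6 at -1.42; with only genes at or above the median level its median was -0.47 at percentile 0.38, so that it stood apart on the low side. Of 14 YAP and TEAD targets 1, CCN1 at 3.60, was higher and 4 were lower, among them AJUBA at -1.93 (median -0.21, percentile 10.04).

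Epithelial markers (median 0.34, percentile 69.1), mesenchymal markers (0.29, 70.8) and pancreatic carcinoma-associated genes (0.25, 46.2) did not stand apart, although SNAI1, a repressor of epithelial genes, was at 4.22, ELF3 at -1.48 and MUC1 at -1.43 at its brightest probe and 0.59 at the other. The list of endocytosis, macropinocytosis and albumin handling had a median of 0.18 (percentile 25.5), with RAB7A at 1.55, SDC1 at 1.55 and CUBN at -1.78. FCGRT, the gene of the neonatal Fc receptor that recycles albumin, was at -0.14 and SPARC at -0.17. The albumin gene ALB was not well above background on any array. In the list of albumin and defensin genes and defensin receptors (median 0.11, percentile 19.9) DEFB4A was at 0.11, CCR6 at -0.26 and MC1R at -2.30. Drug transport and nucleoside drug metabolism genes (median 0.24, percentile 73.0), reference genes (0.50, 65.5) and the markers of pancreatic acinar cells (0.23, 53.7), leukocytes (0.22, 50.1), fibroblasts or stellate cells (-0.08, 34.9) and endothelial cells (0.40, 89.7) did not stand apart. In all, 10 of the 36 lists stood apart on the high side and 1 on the low side, where 1.8 would among random lists, whose genes do not vary together. The numbers were 9 and 2 on HBD2 and 6 and 5 on HSA, so such an excess is not particular to ADDC. Several medians of lists that did not stand apart turned with the scaling. Under normexp with quantile normalization, quantile normalization, cyclic loess and the deposited table, those of ribosomal proteins, metallothioneins, G1/S genes, reference genes and albumin and defensin genes were all below 0. Those of oxidative phosphorylation, RAS-ERK output and fatty acid oxidation were below 0 under 3 of these, and those of fatty acid synthesis and fibroblast markers were above 0 when centred on the median.

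**Figure D3:**
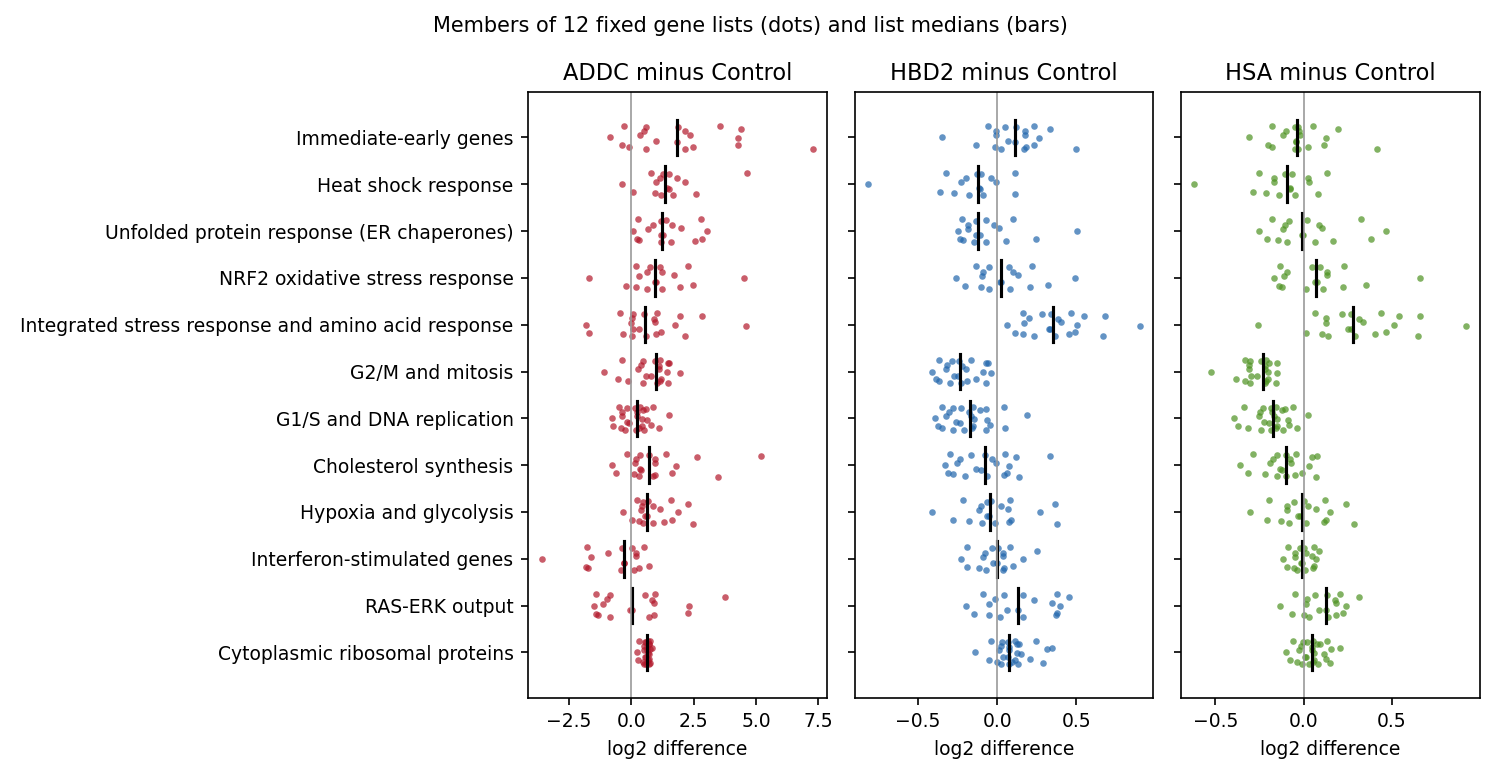
Log2 differences from Control of the measured members (dots) and the median (bars) of 12 gene lists for ADDC, HBD2 and HSA; the horizontal scale differs between panels. On ADDC the median of immediate-early genes is 1.85, and on HBD2 and HSA the G2/M members all lie below 0, with medians of -0.24 and -0.23.

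The comparison of HBD2 with Control gives the background of a different agent for the ADDC values. Of 16710 measured genes, 16 were at least 2-fold higher and 11 at least 2-fold lower, 0.16% in all, and none of 824 probes printed 10 times was. The single-spot SD of the difference was 0.15, and 0.09% of single-spot deviations reached 2-fold by measurement alone, both over all levels. Of the genes counted, 11 of the higher and 8 of the lower lay in the dimmest of 8 level classes (mean level -4.71). Spots near that level had SDs of 0.22 on Control and 0.29 on HBD2. Among the highest that met the naming rule were ribosomal RNA, RNA18SN5 at 11.9-fold (3.57 ± 0.20) and RNA5-8SN5 at 2.32-fold (1.22 ± 0.22), and the pseudogene ACTR3BP5 at 4.10-fold (2.04 ± 0.20). RNA18SN5 was at 2.23 on Control, 4.28 on HSA, 5.81 on HBD2 and 2.08 on ADDC. With 1 array per group a difference in the RNA preparation cannot be told from one in the cells. GDF15 was 1.87-fold higher (0.90 ± 0.20), HAPLN2 1.89-fold and FUT1 1.77-fold. The neuropeptide gene NPY was 4.85-fold lower (-2.28 ± 0.22). LCE2A, DAAM2, WFDC9 and KRTAP10-5 were at -0.95, -0.92, -0.90 and -0.82. For NPY and ACTR3BP5 the Control array was the one apart. NPY was at -1.453 on Control and at -3.565, -3.732 and -3.24 on HSA, HBD2 and ADDC. ACTR3BP5 was at -1.017 on Control and at 1.129, 1.019 and 1.564 on the others. Apart from RNA18SN5, at -0.15 on ADDC, the genes named in this paragraph also lay on the same side of Control on HSA and ADDC.

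Small shifts of whole gene groups were nevertheless measurable on HBD2. All 22 measured genes of the integrated stress response and amino acid response list were higher (median 0.35, percentile 100), with GDF15 at 0.90, NUPR1 at 0.68, SLC7A5 at 0.67 and TRIB3 at 0.55. None of 22 G2/M genes was higher (median -0.24, percentile 0.0), with DLGAP5 at -0.41 and KIF20A at -0.39, and 3 of 26 G1/S genes were (median -0.17, percentile 0.02). The lists of RAS-ERK output (median 0.13, percentile 99.98; FOSL1 at 0.45), immediate-early genes (0.12, 99.97), cytoplasmic ribosomal proteins (0.08, 99.8), pro-apoptotic genes (0.05, 98.8), autophagy and lysosome (0.05, 99.3) and ribosome biogenesis (0.03, 97.8) were also on the high side, as was 1 list that is not described. Of these, autophagy and lysosome, ribosome biogenesis and ribosomal proteins no longer stood apart under quantile normalization (percentiles 96.2, 90.6 and 26.5). The list of albumin and defensin genes and defensin receptors was high too (0.14, 98.99), where the chemokine receptor gene CCR2 was at 1.21, DEFB4A at 0.15 and CCR6 at 0.12. CCR2 was the 1 member at least 2-fold higher, and over the alternatives 0 to 1 members were. It had 1 measured probe, and its level lay under the 25th percentile that the naming rule requires. Its difference is therefore uncertain. The 25 lists that did not stand apart had medians from -0.13 to 0.05. Cytoplasmic ribosomal protein genes had a median of -0.06 under quantile normalization, and olfactory receptor genes, a group chosen after the data were seen whose transcripts are not typical of epithelial cells, had a median of -0.05 at percentile 1.2, so shifts of that size also occurred in genes near background.

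The comparison of HSA with Control gave a picture close to that of HBD2. Of 16852 measured genes, 17 were at least 2-fold higher and 10 at least 2-fold lower, 0.16% in all, and none of 835 probes printed 10 times was. The single-spot SD was 0.15, and 0.08% of single-spot deviations reached 2-fold, both over all levels. Of the genes counted, 13 of the higher and 9 of the lower lay in the dimmest of 8 level classes (mean level -4.79). ACTR3BP5 was 4.43-fold higher (2.15 ± 0.20), RNA18SN5 4.14-fold (2.05 ± 0.20), SPINK8 2.38-fold and FUT7 2.17-fold. GDF15 was 1.89-fold higher (0.92 ± 0.20) and CCN2, the connective tissue growth factor gene, 1.69-fold (0.76 ± 0.21). NPY was 4.32-fold lower (-2.11 ± 0.21), and CYP27B1, CCDC166 and FMN1 were at -0.78, -0.77 and -0.76. As given above, for NPY and ACTR3BP5 the Control array was the one apart.

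On HSA, 21 of 22 genes of the integrated stress response and amino acid response list were higher (median 0.28, percentile 100), with SLC7A11 at 0.66, NUPR1 at 0.65 and TRIB3 at 0.54, and SESN2 at -0.26. None of 22 G2/M genes was higher (median -0.23, percentile 0.0; KIF20A at -0.53), 1 of 26 G1/S genes was (-0.17, 0.0; GINS2 at -0.39), and none of 16 genes of homologous recombination repair was (-0.16, 0.0). Cholesterol synthesis genes were slightly lower (median -0.10, percentile 0.38), with STARD4 at -0.36 and INSIG1 at -0.32. Heat shock genes were at -0.09 (percentile 2.3), which became percentile 9.4 with only the brighter genes kept. RAS-ERK output (0.13, 100), NRF2 targets (0.07, 99.99), ribosome biogenesis (0.05, 99.7) and cytoplasmic ribosomal proteins (0.05, 99.99) lay on the high side, as did 1 list that is not described, and ribosomal proteins turned to -0.02 under quantile normalization. The 25 lists that did not stand apart had medians from -0.14 to 0.05. Olfactory receptor genes had a median of -0.09 at percentile 0.0 on this array. Between HBD2 and HSA the medians of the stress response list and the G2/M list differed by 0.045 (percentile 99.35) and 0.029 (97.01), so both arrays lay on the same side of the single Control array.

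ADDC was also set against each of the other agents. Against HSA, 1320 of 15970 genes were at least 2-fold higher on ADDC and 1695 lower, and against HBD2 1347 of 15918 were higher and 1659 lower, close in number to the comparison with Control. After cyclic loess the splits were 864 and 2036 against HSA and 894 and 2002 against HBD2, but centred on the median they were 1617 and 1537 and 1701 and 1432, and with only the brighter genes 891 and 801 and 955 and 774, with more genes higher than lower. Of 15880 genes measured on all arrays, 1073 lay at least 2-fold above all 3 other arrays on ADDC and 1523 at least 2-fold below them all, or 732 and 1824 after cyclic loess, 1291 and 1337 centred on the median, and 772 and 725 with only the brighter genes. The same count was 3 for Control (NPY and GNRHR2 above and ACTR3BP5 below all others), 3 for HSA and 1 for HBD2. By the naming rule, the genes farthest above all others were again led by NR4A1 and MSMO1 and included GADD45G, a growth arrest gene, at 4.40 from Control at its brightest probe (1.24 at the other), and FOS at 4.38; those farthest below included ZNF75A, PPP1R10, LIAT1 at -4.20 and the antisense RNA ATP6V0E2-AS1 at -4.18. The G2/M list differed in direction between agents, with a median of 0.98 on ADDC against -0.24 on HBD2 and -0.23 on HSA. The integrated stress response list was above 0 on all 3, at 0.55 on ADDC, 0.35 on HBD2 and 0.28 on HSA. Random lists matched on level lay at 0.32, -0.07 and -0.03, and in the main setting the list stood apart on HBD2 and HSA but not on ADDC. Its member CHAC1 was at -1.83 on ADDC against 0.33 on HBD2 and 0.14 on HSA. The differences between arrays were not tested.

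Differences from Control on HSA and HBD2 went together across genes (Pearson's r = 0.61, Spearman's rho = 0.58, 15880 genes). Unchanged arrays that share the Control array gave r = 0.44 in a simulation with spot noise only, and the covariance was 0.017 against a simulated 0.011. For HSA with ADDC, r was 0.093 and the covariance 0.012 against 0.011, and for HBD2 with ADDC r was 0.17 and the covariance 0.028 against 0.012. With no array shared, ADDC minus HSA correlated with HBD2 minus Control at 0.066 and ADDC minus HBD2 with HSA minus Control at -0.038. Among genes measured on all arrays, those at least 2-fold from Control on both HSA and HBD2 were ACTR3BP5 and RNA18SN5 on the high side, where 0.005 genes would be shared by independent lists, and GNRHR2, NODAL and NPY on the low side, where 0.003 would. On the low side HBD2 and ADDC shared 6 genes, among them AQP2, GNRHR2, MLNR, NPY and TENM1, against 0.996 for independent lists. On the high side they shared ACTR3BP5 and RNA5-8SN5, against 0.881. HSA and ADDC shared ACTR3BP5 on the high side, against 0.561, and GNRHR2 and NPY on the low side, against 0.554. Each of these overlaps has the single Control array in common. NPY, GNRHR2 and ACTR3BP5 were at least 2-fold from Control on HSA, HBD2 and ADDC alike, so for them Control was the array apart.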

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

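Probes without a gene symbol lie outside the comparisons of genes, and on the ADDC array they also differed from Control. Of 5649 such probes measured, 13.1% were at least 2-fold apart, 390 of them higher and 349 lower, against 19.2% of probes with a symbol. On the arrays of the other agents the share was 0.26% for HBD2 and 0.30% for HSA. No other signal was seen in data outside the comparisons, and groups of 1 array allow no search for samples far from their group.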

How the results depend on the processing

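The larger number of genes apart on ADDC than on HBD2 or HSA was seen under every alternative run. Under normexp with quantile normalization, which adds an offset that shrinks differences of dim genes, the counts were 1566 for ADDC against Control, 3 for HBD2, 3 for HSA, 1571 for ADDC against HSA, 1513 against HBD2 and 1347 for ADDC apart from all others. With only genes at or above the median level, and so fewer genes, they were 1707, 2, 2, 1692, 1729 and 1497. At 1.5-fold they were 6438, 198, 160, 6573, 6457 and 5362, and at 3-fold 1175, 9, 6, 1165, 1150 and 1006. With all probes and a floor, HBD2 gave 51 and HSA 46; the added genes are dim ones. For ADDC against Control, 2638 of the 2913 genes counted after cyclic loess and 2621 of the 2783 from the deposited table were among the 3044 of the main setting in the same direction. The correlations between differences moved by less than 0.1, and the number of lists standing apart stayed within 10 to 13 of 36. Of list medians that stood apart, those of cytoplasmic ribosomal proteins changed sign under normexp with quantile normalization (HBD2 -0.063, HSA -0.012), quantile normalization (-0.060, -0.023) and the deposited table (-0.060, -0.023), that of interferon-stimulated genes on ADDC with only the brighter genes (0.18), and that of ribosome biogenesis on HBD2 with only the brighter genes (-0.0016); the cause was not tested. Of 4250 alternative values of named genes, 557 moved by more than the single-spot SD and 64 changed sign, none of them for a gene at least 2-fold apart. Of 963 alternative list medians, 98 moved and 104 changed sign, the 8 above for lists standing apart. Apart from the lists of heat shock and 1 other response on HSA, hypoxia, interferon and autophagy on ADDC, autophagy and ribosome biogenesis on HBD2 and ribosomal proteins on both, those standing apart did so under all 9 alternative settings of the values. A further 7 lists on ADDC, 6 on HBD2 and 4 on HSA stood apart only under some alternative. On ADDC these included fatty acid synthesis on the low side under quantile normalization (percentile 1.25), cyclic loess (1.82), normexp and the deposited table, albumin and defensin genes on the low side under normexp (1.64), RAS-ERK output on the low side with only the brighter genes (0.38), and on the high side the proteasome under normexp (98.5) and cyclic loess (98.7), the integrated stress response with the brighter genes (99.7) and the mean of probes (99.83) and pro-apoptotic genes with the mean of probes (98.8). With only the brighter genes the NF-kB list was at percentile 100 on HBD2 (median 0.19) and on HSA (0.11). The others on HBD2 were heat shock, unfolded protein response, oxidative phosphorylation and proteasome on the low side and NRF2 targets on the high side, and on HSA autophagy and metallothioneins on the high side and acinar markers on the low side. With only genes at or above the median level, the acinar, fibroblast and endothelial lists and the dimmer named genes gave no value. Keeping saturated spots changed nothing, since none was saturated. No paired analysis was possible because each group has 1 array. Signal over background limits the low end, where 1062 genes are seen on Control and not on the dimmer ADDC array, and spot noise reached 2-fold in 0.27% of single-spot deviations between ADDC and Control.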

Other observations

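Of the tests in this part, those of immediate-early genes and of the stress response and mitosis lists were chosen after their results had been seen. Gene families grouped by the letters of their symbols, a grouping chosen after the data were seen, were also looked at on the ADDC array. Host genes of small nucleolar RNAs were higher, with 8 of 16 SNHG genes at least 2-fold higher and 1 lower (median 1.04, percentile 100 among matched random lists), led by SNHG1 at 2.88 and SNHG12 at 2.04, with SNHG11 at -1.47. KLF transcription factor genes were higher, with 8 of 15 past 2-fold (median 1.002, percentile 100), among them KLF10 at 2.69 and KLF11 at 2.68, with KLF3 at -3.24. Of 21 genes of the dual-specificity phosphatase family, 7 were higher and 3 lower (median 0.61, percentile 100), with DUSP1 at 4.29 and DUSP2 at 3.94. KLF2, KLF4, KLF6 and DUSP1 are also in the immediate-early list, and DUSP4, DUSP5 and DUSP6 in that of RAS-ERK output. To that extent the KLF and DUSP families are not separate from those lists. Lower families were the transfer RNA methyltransferases, with 7 of 15 TRMT genes at least 2-fold lower and 2 higher (median -0.67, percentile 0.40), and the intraflagellar transport genes, with 5 of 18 IFT genes lower and none higher (median -0.46, percentile 0.85). Of 111 families with at least 15 measured genes, 9 stood apart on the high side and 10 on the low side, where 5.6 would by chance, and 7 and 10 of these also did after cyclic loess. The numbers were similar on the other arrays, with 6 high and 13 low of 120 on HBD2 and 9 high and 13 low of 122 on HSA, so such an excess is not particular to ADDC. Olfactory receptor genes were among the high ones (median 0.30, percentile 99.6), so a shift of that size also occurred in genes near background.

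The zinc finger genes named ZNF were lower on the ADDC array as a family. Of 434 measured, 146 (33.6%) were at least 2-fold lower and 14 higher, against 1758 of all 15977 genes lower, and their median of -0.51 lay below all matched random lists. On HSA and HBD2 the family was at -0.05 each, a small shift that also lay below all matched lists (percentile 0.0). The family was looked at after several members were seen among the lowest genes. A trend with signal level is argued against as the whole cause, since the median was -0.63 after cyclic loess, which removes such trends. A general loss of short-lived mRNAs, as after a stop of transcription, was looked for in the immediate-early list, which had a median of 1.85. Genes of that list are also switched on by a stimulus, which could hide such a loss, so its median does not decide the question. Signal lost from dim probes on the dimmer array stays open in part, because the 171 brighter ZNF genes had a median of -0.30. That median lay below all matched lists yet short of the bound of -0.5 set beforehand. A selective effect of ADDC on ZNF genes is a hypothesis that 1 array cannot separate from lost signal or from a loss of short-lived mRNAs.

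On both HSA and HBD2 the integrated stress response list was higher than on Control and the G2/M list lower. A trend with signal level is argued against, since at least 79.9% of each of the 4 list medians was kept after cyclic loess. The medians of HBD2 against HSA were 0.05 for the stress list and 0.03 for the G2/M list, at most 16.1% of the smaller shift against Control. Small as it is, the stress list difference lay at percentile 99.35, with 16 of 22 genes higher on HBD2, and that of G2/M at 97.01. A Control culture or array that stood apart from the rest would give this picture, and so would a shared response to both agents or to added protein, and these cannot be told apart with 1 Control array. The HSA and HBD2 values are therefore consistent with either.

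Probes of the same gene sometimes went opposite ways on the ADDC array. Of 3625 genes with several measured probes, 57 had a probe at least 2-fold higher and another at least 2-fold lower; JADE2 ranged from -2.33 to 2.52, DNAJB6 from -2.30 to 2.37 and ZC3HAV1 from -1.95 to 2.28. In 100 simulations where all probes of a gene shared the difference of its brightest probe, spot noise gave at most 1 such gene. Among the brighter probes 18 were found against at most 0 simulated. Cyclic loess left 57, which argues against a trend with signal level. Opposed probes were 4.32 times as frequent among pairs of probes designed to different accessions (40 of 1378 pairs, 2.90%) as among pairs with the same accession (26 of 3873, 0.67%). The hypothesis that different transcripts of these genes responded differently would give such a ratio, and misassigned probes could also give it. A difference in accession does not cover the 26 opposed pairs with the same accession. Probe positions were not used here.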
